A study of Mus musculus with 20 samples.

How the data were processed

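Poly-A messenger RNA libraries (TruSeq) of mouse cells labelled spleen were measured in 20 samples, 10 stimulated and 10 untreated, at 10 times from 0 min to 48 h. Messenger RNA and small RNA came from the same tube per the labels, and small RNA was not used here. The deposited values are counts per gene, 1 column per library, which per the submitters' processing notes were made with STAR and HTSeq on GRCm38.p3 (mm10). The versions and settings of STAR and HTSeq are not given in the sources used here, nor is the strand setting, so genes that overlap another gene on the opposite strand, such as Ppifos, are uncertain. A sample sheet by the submitters groups neighbouring times into 5 bins, deposited as midpoints in minutes, and was used only for an alternative.

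The tables hold 41115 genes. Totals per library ran from 36873155 to 60918651 counts as deposited, and 3 counts were taken as the floor of detection, between 0.0492 and 0.0814 CPM (counts scaled to a common library total). This floor covers counting error only. Genes with at least 1 CPM in at least 3 libraries were tested, 12042 of them in the 18 libraries after 0 min and 12139 in all 20. Gene positions came from the GENCODE vM21 annotation of GRCm38.

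Tests, phases, gene lists and the rule for naming genes were set before the data were examined. Differential expression used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, Benjamini-Hochberg adjustment, threshold 0.05). Stimulated and untreated libraries of the same time formed a pair, with time as a factor. Treatment was fitted once over the 9 times after 0 min, and within an early (15 min, 30 min, 1 h), a middle (2, 3 and 6 h) and a late phase (12, 24 and 48 h). The late minus early difference was tested as an interaction. The course over time was tested in all 20 libraries as the interaction of treatment with a natural spline of 3 degrees of freedom of the time index. Change from the early to the late phase was tested within each arm in a fit of 8 groups. The SE of a log2 fold change was its size divided by the square root of F. Values at single times are log2 ratios of CPM plus 0.5 with no test. No paired analysis beyond the pairing by time was possible because the labels carry no replicate numbers.

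Gene lists were written from general knowledge and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within each comparison. Of these, 22 lists had enough expressed members. Lists of immunoglobulin constant regions and mitochondrially encoded genes had 0 members in the tables, and lists of NK cell, neutrophil, erythroid, platelet, mast cell and sex-linked genes were not tested for want of expressed members. Genes were named as the 8 with the largest positive and the 8 with the largest negative log2 fold change (5 and 5 for change over time) among genes past the threshold, with the same sign at every time and a mean CPM of at least 5. For change over time the sign condition was replaced by no overlap between the early and late libraries. For the course over time the 10 genes with the smallest p were named. Gene models without a name of their own, and immunoglobulin and T cell receptor segments, were left out. From these genes the text gives a selection, and some items are not reported here. Members of lists given as examples, Prdm1, Irf4, Il10, Emr1 and the 2 genes apart at 0 min included, were picked after their values were seen.

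Alternatives were RLE size factors, library totals as the only scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 5 CPM in 3 libraries, lane as an additive term, each time left out in turn, the 0 min pair included, differences relative to the 0 min pair, moved phase limits, splines of 2 or 4 degrees of freedom or of log time, camera with an estimated correlation, fry, and a pseudocount of 2 CPM. A spline of time in place of the time factor with and without lane, the submitters' bins, and fits within 1 pair of lanes were added after the data had been seen. The fits were tested on simulated data with 200 changed genes, where 2-fold changes were recovered for 92.5% of genes in the early, 95.4% in the middle and 91% in the late comparison, 85.1% in the late minus early difference and 26.9% in the course over time. False calls were 18 of 196 early, 12 of 194 in the middle, 5 of 180 late, 10 of 162 late minus early and 4 of 69 for the course. The simulated counts held no trend over time and no effect of lane or animal, so they do not test the fits under those.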

Results

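The series followed messenger RNA in mouse cells that the labels give as spleen, at 10 times from 0 min to 48 h, with or without a stimulation cocktail. The cocktail held lipopolysaccharide (LPS, a bacterial ligand of Toll-like receptor 4), interleukin 4 (IL-4) and transforming growth factor beta (TGFb). Per the design text there was 1 treated and 1 untreated mouse, and poly-A libraries of each were made at 0, 15 and 30 min and at 1, 2, 3, 6, 12, 24 and 48 h. This gave 20 libraries, 10 stimulated and 10 untreated, with 1 library per arm and time. Depth was such that 3 counts correspond to between 0.0492 and 0.0814 CPM. Times served in place of replicates, so errors and p-values measure the spread of a difference between times and not between animals. Fold changes below are stimulated over untreated unless stated otherwise, with 3 times per arm in each phase. At no time were both arms in the same sequencing lane. Each arm is 1 animal, so arm and animal cannot be told apart by the design, and arm and lane only in part. Lane 1 held only untreated and lane 4 only stimulated libraries. Lane 2 held stimulated libraries apart from untreated 2 h, and lane 3 untreated ones apart from stimulated 15 min. In a fit with lane, a treatment effect over all times or within a phase rests on those exceptions. A loss of calls there does not show that lane explains a difference.

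Time was the largest source of variation among the 20 libraries. The first principal component of log2 CPM held 50.1% of the variance and placed both 0 min libraries together, at -44.4 for the stimulated and -43.9 for the untreated arm. At 24 h the scores were 60.8 and 39, and at 48 h they were 23.8 and 6.7. Principal component 3 held 13.6% and parted the arms with time, from 1.7 and 0.1 at 0 min to 39.1 in the stimulated and -25.4 in the untreated library at 48 h.

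**Figure D1:**
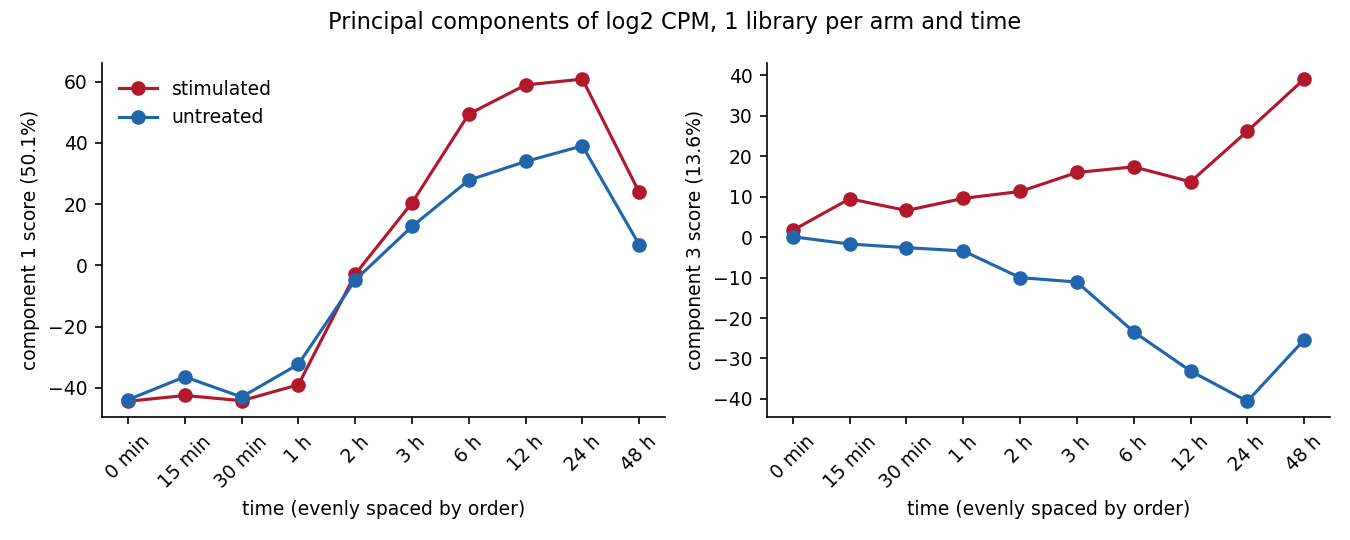
Scores of the 20 libraries on the first principal component (left, 50.1% of variance) and on component 3 (right, 13.6%) of log2 CPM against time, with 1 point per library and 1 line per arm. The arms start together at 0 min and lie apart on component 3 at 48 h.

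The arms began almost alike. Among 9582 genes with a mean CPM of at least 5, at 0 min 1 gene was over 2-fold higher in the stimulated library (Gm6477, log2 ratio 1.79) and 1 over 2-fold lower (Gm11478, -1.18). The same counts were 58 higher and 3 lower at 1 h, 109 and 114 at 6 h, and 277 and 209 at 24 h. At 48 h 282 genes were over 2-fold higher and 160 over 2-fold lower. These per-time values compare single libraries and have no replicate check.

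**Figure D2:**
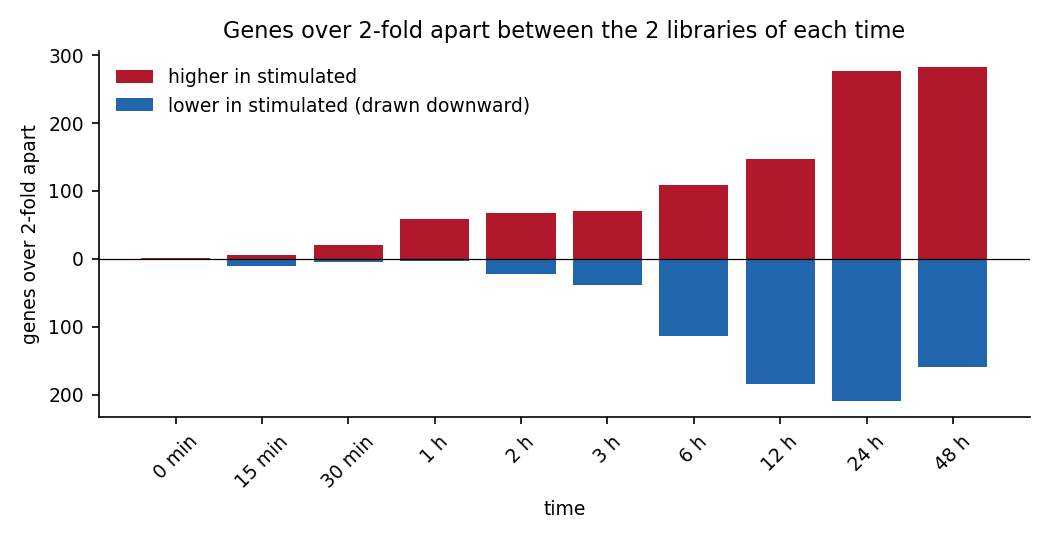
Number of genes over 2-fold higher or lower in the stimulated than in the untreated library at each time, among 9582 genes with a mean CPM of at least 5. The counts go from 1 higher and 1 lower at 0 min to 282 higher and 160 lower at 48 h.

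Early after stimulation (15 min, 30 min and 1 h), immediate early genes were higher in stimulated than in untreated cells. Fos, a subunit of the AP-1 transcription factor, had a log2 fold change of 1.88 ± 0.29 (SE; adjusted p = 0.01). Jun, its partner, had 2.48 ± 0.47 (adjusted p = 0.024), and Zfp36, which promotes decay of cytokine messenger RNAs, had 1.92 ± 0.15 (adjusted p = 0.00036). Cd69, an early activation marker of lymphocytes, was 4.25-fold higher and Tnfaip3, an inhibitor of NF-kB signalling, 2.98-fold higher. Fos fell from 41 CPM at 0 min to 3.93 at 1 h in untreated cells, and from 56.9 to 17.9 in stimulated cells. Of 21 measured immediate early genes, 12 were higher, 0 lower and 9 did not pass, and 18 were higher when adjusted over the list alone. This list stood above other genes (camera adjusted p = 3.3e-34), with adjusted p = 0.15 with an estimated correlation. Among 31 genes of the NF-kB and LPS list, 4 were higher, 0 lower and 27 did not pass, with 6 higher when adjusted over the list alone (camera adjusted p = 7.3e-09; adjusted p = 0.43 with an estimated correlation). Lower genes included Neat1, a nuclear long noncoding RNA, at -1.06 ± 0.11 (adjusted p = 0.0015), and Leng8 at -0.74 ± 0.09 (adjusted p = 0.0033).

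Other lists moved less in the early phase. The cholesterol synthesis list had 0 of 20 higher, 0 lower and 20 that did not pass (0 and 8 when adjusted over the list alone, camera adjusted p = 2e-05, adjusted p = 0.77 with an estimated correlation). The ribosome biogenesis list had 0 of 33 higher, 0 lower and 33 that did not pass (0 and 4 when adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.78 with an estimated correlation). Both lay below other genes, and the next 3 lists above them. The IL-4 and STAT6 list had 3 of 18 higher, 1 lower and 14 that did not pass (3 and 1 when adjusted over the list alone). By camera the adjusted p was 0.004, and adjusted p = 0.56 with an estimated correlation. The TGFb and SMAD list had 1 of 18 higher, 0 lower and 17 that did not pass (5 and 1 when adjusted over the list alone, camera adjusted p = 0.0046, adjusted p = 0.4 with an estimated correlation). The p53 target list had 1 of 17 higher, 0 lower and 16 that did not pass (2 and 0 when adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.4 with an estimated correlation).

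In total 270 genes passed in the early phase, 72 higher and 198 lower, of which 47 differed over 2-fold. The count rested on each of the 3 times, with 58 genes without 15 min (37 higher and 21 lower), 9 without 30 min (4 and 5) and 76 without 1 h (14 and 62). The excess of lower genes was thus lost without 15 min, the only time in lanes 3 and 1, and nearly lost without 30 min, in lanes 4 and 3. The 198 lower genes had median log2 ratios of -0.49 at 15 min, -0.45 at 30 min and -0.36 at 1 h, the times that chose them. The bin of 30 min and 1 h had 24 higher and 2 lower. The immediate early count of 12 fell to 1 without 30 min, 2 without 1 h, 5 with a spline of time, 1 with moved phase limits and 7 in the bin of 30 min and 1 h. With the difference taken relative to the 0 min pair, edgeR called 0 genes (267 at an unadjusted p under 0.05), and with a spline of time and lane in the model it called 0 (815 at an unadjusted p under 0.05).

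In the middle phase (2, 3 and 6 h), Vcam1, an adhesion molecule, was 29.7-fold higher in stimulated cells (log2 fold change 4.89 ± 0.62, adjusted p = 0.00055; -1.25 relative to the 0 min pair, where it had 0.175 CPM in the stimulated and 0 in the untreated library), and Spsb1 10.2-fold higher. Stat5a, a transducer of cytokine signals, was 3.85-fold higher (log2 fold change 1.94 ± 0.09, adjusted p = 9.7e-07), and Cflar, an inhibitor of death receptor signalling, 3.77-fold (1.92 ± 0.08, adjusted p = 9.7e-07). Bcl2l1, which encodes an anti-apoptotic Bcl-2 family protein, was 4.13-fold higher and Gpr183, a receptor that guides B cell migration, 3.66-fold higher. Plk2 and Cbfa2t3 were each 4.28-fold lower, and Hhex, a homeobox transcription factor, was 2.68-fold lower. Prdm1, the transcription factor of plasma cell differentiation, was lower at -1.11 ± 0.13 (adjusted p = 0.00036), while Irf4 was higher at 0.95 ± 0.16 (adjusted p = 0.0023).

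In the lists named for the 3 parts of the cocktail, higher genes outnumbered lower genes in the middle phase. In the NF-kB and LPS list, 18 of 31 genes were higher, 1 lower and 12 did not pass (21 higher and 2 lower when adjusted over the list alone), with Traf1 at 1.82, Cd86 at 1.40 and Nfkbia at 1.37. The camera adjusted p was 5.9e-17, with adjusted p = 0.18 with an estimated correlation. In the IL-4 and STAT6 list, 11 of 18 were higher, 1 lower and 6 did not pass (14 and 2 when adjusted over the list alone), led by Fcer2a at 1.58, Ccl22 at 1.53 and Ciita at 1.32 (camera adjusted p = 1.3e-09; adjusted p = 0.18 with an estimated correlation). In the TGFb and SMAD list, 8 of 18 were higher, 0 lower and 10 did not pass (8 and 1 when adjusted over the list alone), among them the feedback inhibitors Smad7 at 0.75 and Skil at 0.78 (camera adjusted p = 0.00037; adjusted p = 0.18 with an estimated correlation). Of 33 ribosome biogenesis genes, 20 were higher, 0 lower and 13 did not pass (21 higher when adjusted over the list alone), by small amounts such as 0.27 for Ncl and 0.28 for Npm1. Their camera adjusted p was 8.7e-09, with adjusted p = 0.48 with an estimated correlation. Leaving out 3 h lowered the IL-4 count to 5, the TGFb count to 5 and the ribosome biogenesis count to 6. Without 2 h these counts were 7, 7 and 12, and without 6 h they were 6, 5 and 14. The NF-kB, IL-4, TGFb and ribosome biogenesis lists had 3, 2, 0 and 0 higher genes relative to the 0 min pair, and the same numbers with a spline of time and lane. Ribosome biogenesis had 1 with a spline alone, 2 with moved phase limits and 0 in the bin of 2 and 3 h, and TGFb 4, 4 and 2. IL-4 had 3 in that bin and 7 with library totals only.

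The middle phase had 2463 genes past the test, 1228 higher and 1235 lower (49.9% higher, and 25% higher with library totals as the only scaling), with 286 over 2-fold. There were 899 without 3 h and 1321 without 6 h, 43 relative to the 0 min pair, and 21 with a spline of time and lane in the model.

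Late after stimulation (12, 24 and 48 h), Vcam1 was 177-fold higher in stimulated cells (7.47 ± 0.53, adjusted p = 4.9e-06), against 37 counts in all in the 3 untreated libraries, 0 of them at 48 h. Fcer2a, the low-affinity IgE receptor, was 24.7-fold higher (4.63 ± 0.45, adjusted p = 2.5e-05) and Gpr15, a homing receptor, 19-fold higher (4.25 ± 0.30, adjusted p = 4.7e-06).

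Other genes were lower late. Cd22, an inhibitory co-receptor of the B cell antigen receptor, was 5.69-fold lower in stimulated cells (-2.51 ± 0.19, adjusted p = 7.6e-06), with 31 CPM against 243 at 24 h. Pde2a, a cyclic nucleotide phosphodiesterase, was 9.24-fold lower and Hepacam2 6.44-fold lower. Prdm1 was lower at -2.01 ± 0.14 (adjusted p = 4.7e-06) and the cytokine gene Il10 at -2.44 ± 0.25 (adjusted p = 3.9e-05).

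**Figure D3:**
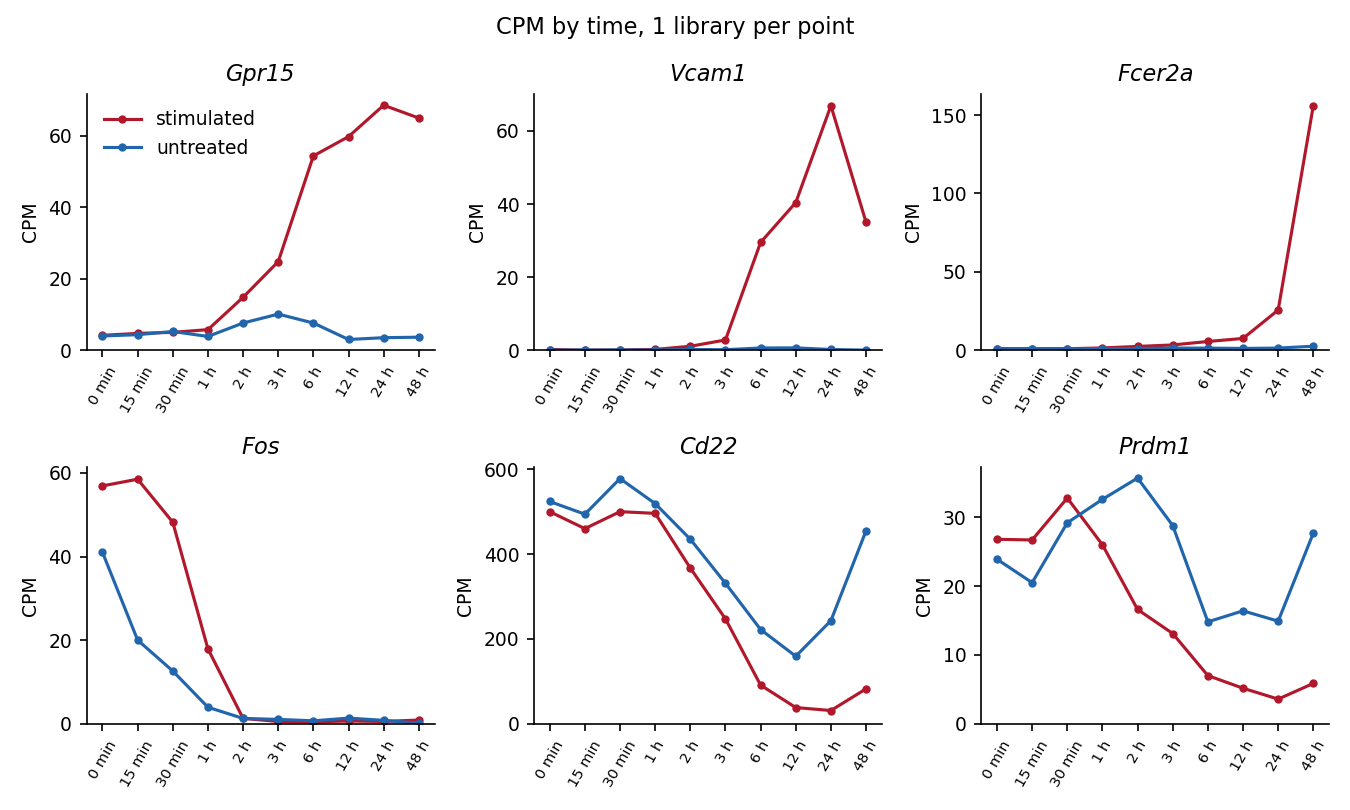
CPM of Gpr15, Vcam1, Fcer2a, Fos, Cd22 and Prdm1 at each time, with 1 point per library and 1 line per arm. Gpr15 reached 68.6 CPM at 24 h in the stimulated arm against 3.49 in the untreated arm, and Cd22 fell to 31 CPM at 24 h in the stimulated arm against 243.

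In the late phase 13 of 14 hypoxia genes were higher, 0 lower and 1 did not pass (13 when adjusted over the list alone), with Bnip3 at 1.51 and P4ha1 at 0.85. Of 17 glycolysis genes 14 were higher, 0 lower and 3 did not pass (14 when adjusted over the list alone), with the lactate exporter Slc16a3 at 1.82, Pfkl at 0.83 and Hk2 at 0.80. Both lists had a camera adjusted p of 4.4e-08, with adjusted p = 0.35 with an estimated correlation for hypoxia and adjusted p = 0.47 with an estimated correlation for glycolysis. The IL-4 and STAT6 list had 11 of 18 higher, 2 lower and 5 that did not pass (12 and 2 when adjusted over the list alone), with Ccl22 at 2.07 and Ciita, the regulator of MHC class II genes, at 1.73. Its camera adjusted p was 3.5e-07, with adjusted p = 0.35 with an estimated correlation. The NF-kB and LPS list had 17 of 31 higher, 5 lower and 9 that did not pass (21 and 5 when adjusted over the list alone), with Nfkb2 at 1.53 and Il10 and Tlr4 among the lower genes (camera adjusted p = 1.2e-06; adjusted p = 0.47 with an estimated correlation). The TGFb and SMAD list had 11 of 18 higher, 3 lower and 4 that did not pass (11 and 3 when adjusted over the list alone), with Ldlrad4 at 1.91 and Smad7 at 1.07 (camera adjusted p = 0.0023; adjusted p = 0.35 with an estimated correlation).

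Of 12 B cell markers, 0 were higher, 4 lower and 8 did not pass (4 lower when adjusted over the list alone), led by Cd22 and with Ebf1 at -0.72 (camera adjusted p = 0.023, and adjusted p = 0.55 with an estimated correlation). The list had a median log2 fold change of -0.09 against a mean of -0.37. Its median log2 ratio was -0.33 at 12 h, -0.13 at 24 h and 0.13 at 48 h, so a general fall was not seen. Among 9 macrophage and monocyte markers, 5 were higher, 2 lower and 2 did not pass (5 and 3 when adjusted over the list alone; camera adjusted p = 0.37). Of these Emr1, which encodes F4/80, reached 36.1 CPM in the stimulated arm at 48 h against 1.3, and Hmox1 was lower at -0.68.

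The other lists were mixed or small in the late phase. Of 13 plasma cell genes 2 were higher, 6 lower and 5 did not pass (2 and 6 when adjusted over the list alone; camera adjusted p = 0.2), with Prdm1 lower, Irf4 higher at 0.54 and Slamf7 higher at 1.00. Of 10 germinal center genes 2 were higher, 5 lower and 3 did not pass (2 and 6 when adjusted over the list alone; camera adjusted p = 0.38), with the death receptor gene Fas at 3.65 and Rgs13 at -1.52. Of 20 resting naive B cell genes 7 were higher, 3 lower and 10 did not pass (7 and 3 when adjusted over the list alone; camera adjusted p = 0.55), with Tcf7 at 3.47 and Cd24a at -1.82. Of 46 cell cycle genes 5 were higher, 13 lower and 28 did not pass (5 and 14 when adjusted over the list alone; camera adjusted p = 0.29), with Ccnd2, a cyclin of G1, at 2.12 and E2f2 at -1.05. Of 16 interferon stimulated genes 3 were higher, 2 lower and 11 did not pass, with Oasl2 at 2.52 (3 and 2 when adjusted over the list alone; camera adjusted p = 0.37). The camera adjusted p was 0.14 for the 17 p53 targets (6 higher, 3 lower), 0.095 for the 20 cholesterol synthesis genes (6 and 0), 0.37 for the 25 genes of the unfolded protein response (1 and 5) and 0.37 for the 12 heat shock genes (3 and 0). It was 0.37 for the 8 T cell markers (1 and 2), 0.37 for the 5 dendritic cell markers (3 and 1) and 0.14 for the 5 markers of stroma and endothelium (3 and 0).

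The late phase had 4351 genes past the test, 2149 higher and 2202 lower (49.4% higher, and 40.4% with library totals as the only scaling). Of these 846 differed over 2-fold (404 higher and 442 lower). There were 847 relative to the 0 min pair and 185 with a spline of time and lane in the model, where the hypoxia, glycolysis, IL-4, NF-kB and TGFb lists had 0, 1, 2, 3 and 0 higher genes. Relative to the 0 min pair these lists had 4, 9, 5, 10 and 3. Of genes higher in the middle phase 711 were also higher late, against 219.1 for independent lists, and 830 were lower in both, against 225.8. The 2 phases share the animals and 1 estimate of spread, so their lists are not independent and the excess over these numbers was not tested.

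**Figure D4:**
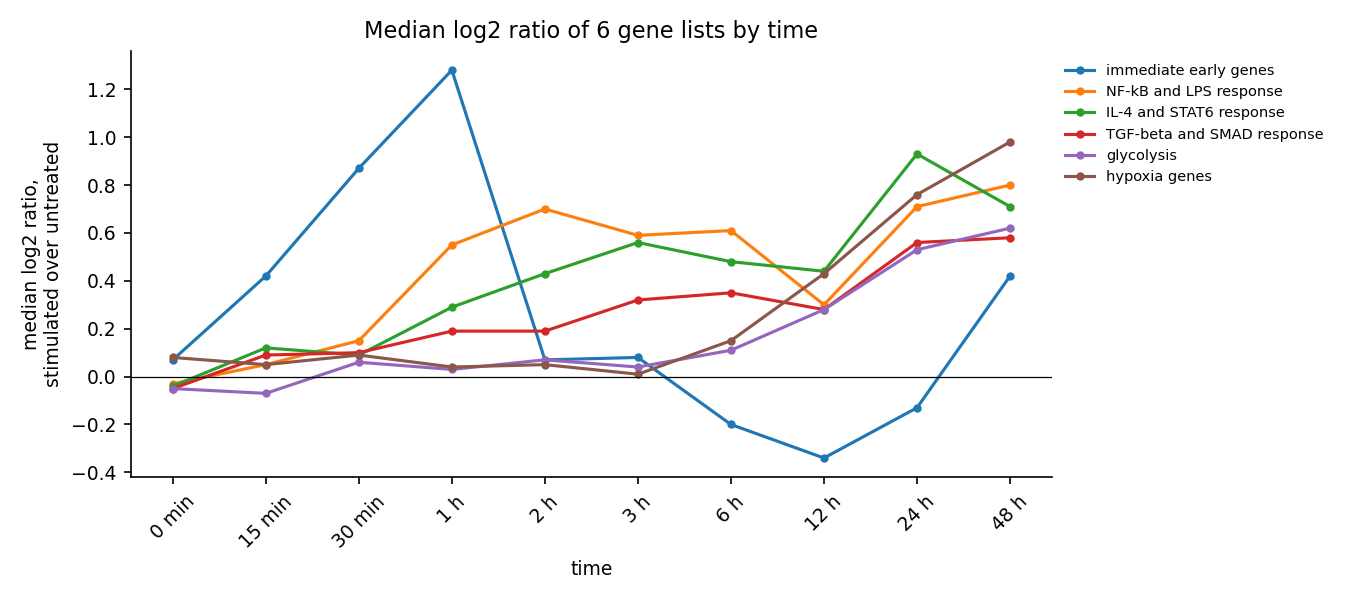
Median log2 ratio of stimulated over untreated CPM for 6 gene lists at each time, with 1 library per arm and time. Immediate early genes peak at 1.28 at 1 h, while hypoxia genes lie near 0 until 3 h and reach 0.98 at 48 h.

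Across all 9 times after 0 min, Rnf19b, a ubiquitin ligase, was 5.1-fold higher (2.35 ± 0.35, adjusted p = 0.0021) and Neat1 2.95-fold lower (-1.56 ± 0.12, adjusted p = 0.00016). Fcer2a, Icosl, Tbc1d4, Fas, Arid5a and Tcf7 were between 2.9 and 4.42-fold higher, and Cd22, Pou6f1 and Wnt16 were about 2-fold lower. The NF-kB and LPS list had 19 of 31 genes higher, 0 lower and 12 that did not pass (20 and 1 when adjusted over the list alone; camera adjusted p = 1.3e-11; adjusted p = 0.095 with an estimated correlation). The IL-4 and STAT6 list had 12 of 18 higher, 2 lower and 4 that did not pass (14 and 2 when adjusted over the list alone). Camera gave it an adjusted p of 6.4e-07, and adjusted p = 0.095 with an estimated correlation. The TGFb and SMAD list had 11 of 18 higher, 2 lower and 5 that did not pass (13 and 2 when adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.095 with an estimated correlation). The hypoxia list had 3 of 14 higher, 0 lower and 11 that did not pass (8 and 0 when adjusted over the list alone, camera adjusted p = 0.00049, adjusted p = 0.71 with an estimated correlation). The immediate early list had 4 of 21 higher, 0 lower and 17 that did not pass (4 and 0 when adjusted over the list alone). By camera the adjusted p was 0.00054, and adjusted p = 0.71 with an estimated correlation. The glycolysis list had 4 of 17 higher, 0 lower and 13 that did not pass (10 and 0 when adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.71 with an estimated correlation). In all 2680 genes passed, 1274 higher and 1406 lower (47.5% higher, and 27.3% with library totals as the only scaling). There were 1571 without 6 h, 1673 without 24 h and 1737 without 12 h, and with a spline of time and lane edgeR called 0 genes (753 at an unadjusted p under 0.05).

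The difference between arms itself changed from early to late for 2377 genes, 1230 upwards and 1147 downwards. Neurl3, Fcer2a and Fas moved towards the stimulated arm, by 4.95 ± 0.66 for Neurl3 and 3.45 ± 0.40 for Fas on the log2 scale. The immediate early list moved the other way, with 0 of 21 genes up, 9 down and 12 that did not pass (12 down when adjusted over the list alone; camera adjusted p = 3e-07; adjusted p = 0.52 with an estimated correlation). The glycolysis list had 11 of 17 up, 0 down and 6 that did not pass (13 and 0 when adjusted over the list alone, camera adjusted p = 3e-07, adjusted p = 0.52 with an estimated correlation). The hypoxia list had 9 of 14 up, 0 down and 5 that did not pass (11 and 0 when adjusted over the list alone). Camera gave it an adjusted p of 2.5e-06, and adjusted p = 0.52 with an estimated correlation. The cholesterol synthesis list had 8 of 20 up, 0 down and 12 that did not pass (13 and 1 when adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.61 with an estimated correlation). The IL-4 and STAT6 list had 8 of 18 up, 2 down and 8 that did not pass (8 and 3 when adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.52 with an estimated correlation). The ribosome biogenesis list had 4 of 33 up, 0 down and 29 that did not pass (0 and 0 when adjusted over the list alone). By camera the adjusted p was 0.029, and adjusted p = 0.61 with an estimated correlation. Within the times sequenced in lanes 2 and 1, the difference at 12 and 24 h minus that at 0 min and 1 h passed for 1212 genes. Within lanes 4 and 3, 6 and 48 h minus 30 min and 3 h, edgeR called 0 genes (823 at an unadjusted p under 0.05). Called genes of the comparison had a median size of 0.94 of their reported one in lanes 2 and 1, and 0.63 in lanes 4 and 3 (2304 of 2330 with the same sign), in fits that share libraries with it. In lanes 4 and 3, the middle times 3 and 6 h stood in for an early and a late time. The sizes and calls of the lane pairs are therefore not a like comparison. The count was 1372 without 15 min, 1393 without 30 min, 1518 without 1 h, 1526 with lane as an additive term, and 442 with a spline of time and lane.

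A smooth course over all 10 times differed between the arms for 677 genes (1224 with DESeq2, and 426 with a spline of 2 degrees of freedom). Cyp11a1, the enzyme that begins steroid synthesis, stayed between 81.6 and 93.3 CPM in the untreated arm and fell from 85.4 to 11.7 CPM in the stimulated arm (adjusted p = 1.7e-07). Acadm, an enzyme of fatty acid oxidation, went from 51.6 to 217 CPM in the stimulated and from 43.1 to 52.1 in the untreated arm (adjusted p = 3.2e-07). Tnni1 rose to 161 CPM against 8.62 (adjusted p = 3.2e-07).

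Both arms also changed with time. From the early to the late phase, Fos fell 16.6-fold in untreated and 60.6-fold in stimulated cells, and Fosb and Nr4a1 fell in both. The cholesterol synthesis gene Idi1 rose by 2.10 ± 0.40 in untreated (adjusted p = 0.0015) and by 3.14 ± 0.42 in stimulated cells (adjusted p = 4.9e-05). Of 20 cholesterol synthesis genes, 19 rose, 0 fell and 1 did not pass in each arm (20 rose when adjusted over the list alone), with camera adjusted p of 1.2e-08 in untreated and 2.3e-08 in stimulated cells. With an estimated correlation these were adjusted p = 0.37 with an estimated correlation in untreated and adjusted p = 0.66 with an estimated correlation in stimulated cells. Of 46 cell cycle and DNA replication genes, 37 rose, 2 fell and 7 did not pass in untreated cells (38 and 2 when adjusted over the list alone; camera adjusted p = 2.3e-10; adjusted p = 0.31 with an estimated correlation). In stimulated cells 37 rose, 1 fell and 8 did not pass (38 and 1 when adjusted over the list alone; camera adjusted p = 1.5e-06; adjusted p = 0.66 with an estimated correlation). Of 22 immediate early genes 0 rose, 14 fell and 8 did not pass in untreated cells (15 fell when adjusted over the list alone; camera adjusted p = 2.7e-06; adjusted p = 0.31 with an estimated correlation). In stimulated cells 0 rose, 16 fell and 6 did not pass (18 fell when adjusted over the list alone; camera adjusted p = 2.7e-10; adjusted p = 0.24 with an estimated correlation).

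The glycolysis list had 11 of 17 that rose, 0 that fell and 6 that did not pass in untreated cells (11 and 0 when adjusted over the list alone, camera adjusted p = 3.3e-06, adjusted p = 0.31 with an estimated correlation). The glycolysis list had 13 of 17 that rose, 0 that fell and 4 that did not pass in stimulated cells (13 and 0 when adjusted over the list alone, camera adjusted p = 2.7e-10, adjusted p = 0.24 with an estimated correlation). The ribosome biogenesis list had 16 of 33 that rose, 0 that fell and 17 that did not pass in untreated cells (16 and 0 when adjusted over the list alone). Camera gave it an adjusted p of 0.00072, and adjusted p = 0.51 with an estimated correlation. The ribosome biogenesis list had 22 of 33 that rose, 0 that fell and 11 that did not pass in stimulated cells (22 and 0 when adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.69 with an estimated correlation). The heat shock list had 8 of 12 that rose, 1 that fell and 3 that did not pass in untreated cells (8 and 1 when adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.48 with an estimated correlation). The heat shock list had 10 of 12 that rose, 1 that fell and 1 that did not pass in stimulated cells (10 and 1 when adjusted over the list alone). By camera the adjusted p was 0.039, and adjusted p = 0.69 with an estimated correlation. The TGFb and SMAD list had 2 of 18 that rose, 7 that fell and 9 that did not pass in untreated cells (2 and 7 when adjusted over the list alone, camera adjusted p = 0.0094, adjusted p = 0.31 with an estimated correlation). The stroma marker list had 0 of 5 that rose, 5 that fell and 0 that did not pass in untreated cells (0 and 5 when adjusted over the list alone, camera adjusted p = 0.0094, adjusted p = 0.31 with an estimated correlation). The macrophage marker list had 0 of 9 that rose, 4 that fell and 5 that did not pass in untreated cells (0 and 5 when adjusted over the list alone). Camera gave it an adjusted p of 0.034, and adjusted p = 0.46 with an estimated correlation. The hypoxia list had 7 of 14 that rose, 1 that fell and 6 that did not pass in stimulated cells (8 and 1 when adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.69 with an estimated correlation).

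In untreated cells 5176 genes passed between the early and late phases, 2745 higher late and 2431 lower (53% higher, and 39.1% with library totals only), and in stimulated cells 6664, 3549 higher and 3115 lower (53.3%, and 40.1% with library totals only). Genes higher late in both numbered 2335, against 802.5 for independent lists, and genes lower in both 1839, against 623.8. Without any overlap between the 3 early and 3 late libraries there were 7223 genes (59.5%) in untreated and 7679 (63.3%) in stimulated cells, where chance gives 10%. The untreated count was 3417 without 24 h and 3431 without 30 min. Going from TMM to library totals only shifted the late over early log2 ratios of all genes by -0.113 in untreated and -0.146 in stimulated cells.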

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

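The late minus early tests and the splits of libraries were planned before the data were examined, and the tests of explanations in the next 2 paragraphs were chosen after the result was seen. Among 24 tests for an outlying value, 0 met the limit, where chance gives 5%. These took measures of the libraries within each arm, and the log2 ratios across times of 16 genes named over all times. Those genes were chosen for the same sign at every time, so they are not a random draw. The results below came forward because the difference between the arms was itself different late and early, among 16 genes and 22 lists tested. Larger late than early was the difference of Rnf19b (by 2.24, adjusted p = 0.0036), Neurl3 (4.95, 0.00059), Fcer2a (4.38, 0.0017), Icosl (3.1, 0.00027), Tbc1d4 (3.14, 0.00014), Fas (3.45, 3e-04), Arid5a (2.88, 0.00017) and Tcf7 (3.26, 0.00027). It moved down for Neat1 (-0.67, adjusted p = 0.0094), Ahnak2 (-1.56, 0.0073), Pstpip2 (-2.48, 4e-04), Cd22 (-2.38, 0.00024), Pou6f1 (-1.87, 0.00054) and Wnt16 (-1.89, 0.00064). List medians moved by -1.4 for immediate early genes (adjusted p = 3e-07), 0.52 for IL-4 and STAT6 (0.00017), 0.12 for ribosome biogenesis (0.029), 0.41 for glycolysis (3e-07), 0.4 for cholesterol synthesis (0.00013), 0.71 for hypoxia (2.5e-06) and -0.18 for B cell markers (0.0051). None of these list calls held with an estimated correlation, where in the same order adjusted p = 0.52, 0.52, 0.61, 0.52, 0.61, 0.52 and 0.53 with an estimated correlation.

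For genes over 2-fold apart in the late phase, a fixed difference of lanes or animals would show at every time sequenced in the same lanes. Signed by their late direction, the 846 genes had a median log2 ratio of 0.01 at 0 min (lanes 2 and 1, as at 12 and 24 h) and 0.08 at 30 min (lanes 4 and 3, as at 48 h), against 1.31 at 48 h. This argues against a fixed effect of these lanes and against a constant difference between the animals. The labels do not say whether the stimulated 0 min library was taken before or after the cocktail was added. With 1 animal per arm, a divergence of the animals or cultures for a reason other than the cocktail could not be told from its effect.

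For the 198 genes lower in the early phase, the median log2 ratio was already -0.12 at 0 min, against a median early log2 fold change of -0.43, so part of the difference could have been there at 0 min and the question stays open. The calls rest on single pairs, with 21 genes lower without 15 min and 5 without 30 min. The 198 genes had median log2 ratios of -0.49, -0.45 and -0.36 at 15 min, 30 min and 1 h, the times that chose them. From 2 h on the medians lay between -0.21 and -0.34, with 77.8% to 84.3% of the genes lower. At 0 min 85.4% were lower. Of the 198 genes 48 (24.2%) were gene models without a name, against 12.7% of all tested genes. A larger share of nuclear RNA in the untreated libraries could lower such genes, but Malat1, another nuclear RNA, had -0.5 ± 0.13 (adjusted p = 0.071) against -1.06 for Neat1, which does not decide it.

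Exchanging the arms at some times gave as many genes as the real grouping in 1 of 100 splits over all times (the real one itself, 2680 genes, highest other 1). An exchange turns any difference between the arms at those times into spread, so this count does not bear on chance. For the course over time, exchanging the arms gave as many genes in 3 of 100 (677, highest other 723). The split with 723 genes exchanged the arms at every time from 15 min to 3 h, and one with 690 genes at 15 and 30 min. Both keep the late difference whole, so the count for the course does not bear on chance. For the late minus early difference, exchanging the arms gave as many genes in 2 of 32 (2377, highest other 3657). That other split exchanged the arms at all 3 late times, which keeps the late difference whole, so this count does not bear on chance. The 24 splits that parted the late times called 0 genes each. They turn the late difference itself into spread, so they do not bear on chance either. The other comparisons had 10 splits of their 6 libraries each, which regroup libraries across times and ignore the pairing by time, and are too few to judge; the real one was 1 of 10 in each. The highest other counts were 1 for early (real 270), 44 for middle (2463), 2 for late (4351), and 0 for both arms over time (5176 untreated, 6664 stimulated).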

How the results depend on the processing

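RLE factors, library totals, limma-voom and the stricter filter left every total of genes within 1.5 times, but with library totals the higher genes went to 760 over all times and 669 in the middle phase (lower 2006), and with limma-voom to 121 early. Of 481 named values RLE kept 479, limma-voom 469, library totals 464 and DESeq2 463 on their side of the threshold. A smaller share kept it in some settings that were run on part of these values. With a spline of time and lane 248 kept it, 209 lost their call and 2 were reversed. Relative to the 0 min pair 279 kept it, 161 lost their call and 1 was reversed. In the bin of 2 and 3 h 91 kept it, 55 lost their call and 1 gained one. The cause was not tested for any value below unless stated. DESeq2 gave 426 early genes and 1224 for the course over time, and no filter gave 747 early, from a fit with some extremely small p-values, so that this count is uncertain. A spline of time gave 1689 over all times, 38 early, 1247 middle, 2331 late and 861 late minus early; with lane added these were 0, 0, 21, 185 and 442. Both were chosen after seeing the data, as were the bins (26 at 30 min and 1 h, 211 at 2 and 3 h, 1858 at 24 and 48 h, fewer libraries each) and the lane pairs (1212 in lanes 2 and 1, 0 in lanes 4 and 3, fewer libraries each). The fit in lanes 4 and 3 also included middle times. Lane as an additive term with time as a factor gave 1526 late minus early; over all times and within each phase the treatment effect cannot be estimated with it, because a shift of it can be taken up by the lanes. Relative to the 0 min pair there were 0 early, 43 middle and 847 late genes. That contrast sets 3 pairs against 1 pair. Its error therefore also includes the spread of a single pair, beyond counting error. Moved limits gave 62 early and 458 middle, and a spline of 2 degrees of freedom 426 for the course.

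Leaving out each time gave 1571 to 2767 over all times, 9 to 76 early, 899 to 1699 middle, 3056 to 4266 late, 1372 to 2622 late minus early, 464 to 751 for the course, 3417 to 5533 untreated and 5406 to 6949 stimulated. Lists called with an estimated correlation were 0 in all 7 comparisons, and with fry 0 early, 12 late, 17 in untreated and 15 in stimulated cells. With a pseudocount of 2 CPM 1 gene was over 2-fold apart at 0 min and 6 at 15 min, since it shrinks ratios of low values. Among the named values, reversed were Hmox1 in the middle phase (0.06 with a spline, 0.01 with lane added), Klf6 in the middle phase (0.12 with moved limits), Fads2 in the late phase (-0.25 with spline and lane) and Vcam1 in the middle phase (-1.25 relative to 0 min, where it had 0.175 and 0 CPM). Of all called genes, 93 over all times and 56 late changed sign with spline and lane, and 52 late, 24 middle and 9 early relative to the 0 min pair; other settings turned at most 26 (lanes 4 and 3).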

Other observations

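The test in this part was chosen after the result was seen. The T cell receptor complex genes Cd3e, Cd3d and Cd3g had at most 0.224, 0.527 and 0.681 CPM in any library. Lists of markers of non-B cells were mostly low. The median of mean CPM was 0.673 for T cell, 0.36 for macrophage and monocyte, 0.781 for dendritic cell, 0.00801 for NK cell and 0.0238 for neutrophil markers. Exceptions that were not low included Mpeg1 (147 to 644 CPM), Ctss (185 to 292), Madcam1 (73.4 to 211) and Cd5 (32.4 to 69.1). The proliferation genes Mki67 and Top2a had at least 708 and 547 CPM in every library, 0 min included. The highest count of the 4 Y-linked genes was 0, which argues against cells with a Y chromosome. Xist, which ordinary female cells express, was at most 0.377 CPM as well, so the sex of the cells was left open. The labels do not say whether cells were purified, cultured beforehand or of a cell line.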
